A study of Solea solea with 39 samples.

How the data were processed

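RNA of 39 pools of whole common sole larvae was measured, 1 array per pool, at 10 ages. Groups and replicate letters were taken from the sample labels, and the series design describes the replicates of an age as biological ones. Per the labels, RNA was extracted with a column kit, amplified and labelled with Cyanine 3 by Agilent's 1-colour protocol.

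Each array's file is the scanner output of Agilent Feature Extraction, per the file headers, with spatial and multiplicative detrending and surrogate values for dim spots switched on. The deposited intensity used here is the processed signal, which per the file headers is background-subtracted and detrended within the array but not scaled between arrays. The mean spot intensity and the median local background intensity deposited beside it are on the scanner's own linear scale. The authors also deposited processed intensity values in a single table with a column for each array. In each column its order of probes followed the scanner values (lowest Spearman correlation 0.99968), and all 39 columns matched their own array best. These values are linear, with column medians between 492.3 and 638.7; how the authors scaled them between arrays, and any centring, is not given in the sources used here.

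The array holds 14674 probes of 60 bases (14654 distinct sequences) and 536 control spots, which were left out. Probe IDs begin with N (5774 probes), P (5208), AS (1846) or S (1846); the meaning of these prefixes is not given in the sources used here. The files give each probe's ID in place of a gene name, and no gene table used here lists the IDs.

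The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. Spots with the software's flags for uneven or outlying pixels were set to missing. A probe was tested if it was well above background, by the software's flag, on every array of at least 1 age, which kept 13253 probes and left out 1421. A linear model with a mean for each age was fitted to all 39 arrays with limma 3.58.1 (lmFit and eBayes, in R 4.3.3, 29 residual degrees of freedom), so that all ages share the estimate of the spread. P-values are two-sided. They were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and a probe that passes is written as called, or as having risen or fallen. The comparisons were the moderated F test over the 10 ages and 15 pairs of ages: 33 against 1, 4 against 1, 11 against 4, 18 against 11 and 33 against 18 dph as the main ones, the other steps between neighbouring ages, and 11 against 6 and 18 against 13 dph, which pass over the ages of the second run.

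Where a probe was not well above background on any array of an age, only a bound is given, as "at least N-fold". It is the bright age's mean against the dim age's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. The model's adjusted p stands beside it. Counts of probes by fold and medians of change use the model's age means and apply no bound.

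Named probes were chosen by a rule fixed before the data were examined: for each main comparison, the 10 largest rises and 10 largest falls among called probes whose arrays did not overlap between the ages and which were well above background on every array of at least 1 of the 2 ages. The rule asked for genes with names, and without names it was applied to probe IDs. Of each 10, the text prints 2: the largest change measured on both sides and the highest bound, or 2 of a kind where the other was missing. This choice of 2 was made after the data were examined.

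Gene lists for immune and other functions, their shift tests and the onset counts of immune genes had been planned and could not be run without gene names. In place of the onset counts, lasting rises and falls of all tested probes were counted, and probes with an inner peak or trough: an age between 1 and 33 dph, among the first-run ages, that is above or below both. These 4 counts were chosen after the files had been read.

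Slides and scan runs were read from the files, a run by the last field of the scan date alone. Scanning sessions within a run were not told apart. The first run held 31 arrays of 8 ages on 4 slides, and the second held the 8 arrays of 8 and 15 dph on 5 slides. Slide was tried as a fixed block for pairs of first-run ages, as a random block (duplicateCorrelation, within-slide correlation 0.0205) for the others, and counts were made within single slides that held both ages. Other alternatives were quantile normalization, normexp background correction with an offset of 50 and quantile normalization, the authors' table, no filter on dim probes, fewer arrays in the model, the replicate block, a minimum of 2-fold, a mean-variance trend in eBayes, and leaving out each array.

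The model was tested on simulated data for 33 against 1 dph, drawn from the residual spread of 13109 real probes with 200 of them changed. It recovered 92 of 100 probes changed by 3-fold and 60 of 100 changed by 1.5-fold, with 13 calls among unchanged probes. The simulation was a single draw of normally distributed noise, without a background floor, slides or scaling. It changed far fewer probes than the 10333 called in the real comparison, so these rates need not hold there. Tables were handled with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.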

Results

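Whole larvae of the common sole (Solea solea), a flatfish, were sampled in pools at 10 ages between 1 and 33 days post hatching (dph): at 1, 4, 6 and 8 dph, then at 11, 13, 15 and 18 dph, and last at 24 and 33 dph. Total RNA of each pool was labelled with Cyanine 3 and hybridised to a 1-colour array of 60-base probes. A pool held 10 larvae up to 15 dph and 5 larvae from 18 dph on, and 39 arrays were analysed. There were 4 replicate pools per age, lettered A to D, except at 13 dph, where 3 pools (B, C and D) were available and the fourth was not analysed here. Mean numbers of probes well above background per array lay between 12403 ± 854 (SD, n = 4) at 18 dph and 13286 ± 130.5 (SD, n = 4) at 11 dph, of 14674 probes. The number of arrays per age limits the precision of every value given here.

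By its title, the series asks when genes relevant to immunity are first expressed. The files pair no probe with a gene name, and 0 of the probe IDs matched the gene table used here. Immune genes were therefore not picked out, and the time course is described for all probes, with single probes named by their ID and sequence. Probe IDs are those of the array design, in which isotig and contig numbers name assembled transcripts.

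The first principal component of the expression profile followed age. It held 56.7% of the variance over 13109 probes, and its mean score rose at each successive age, from -133.6 ± 1.04 (SD, n = 4) at 1 dph to -3.05 ± 2.80 (SD, n = 4) at 11 dph and 87.9 ± 2.83 (SD, n = 4) at 33 dph. The second component, with 17.1%, rose and fell again: it was lowest at 1 dph, at -75.96 ± 0.956 (SD, n = 4), highest at 6 dph, at 52.5 ± 5.90 (SD, n = 4), and stood at -39.45 ± 2.07 (SD, n = 4) at 33 dph. The third, with 6.06%, had its lowest mean at 33 dph, at -46.9 ± 13.8 (SD, n = 4), where the pools were also furthest apart on this component. Pools of the same age correlated at a median r of 0.987 (57 pairs, lowest 0.977), across probes, which are not independent replicates. Pools of different ages correlated at a median r of 0.920 (684 pairs, lowest 0.714).

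**Figure D1:**
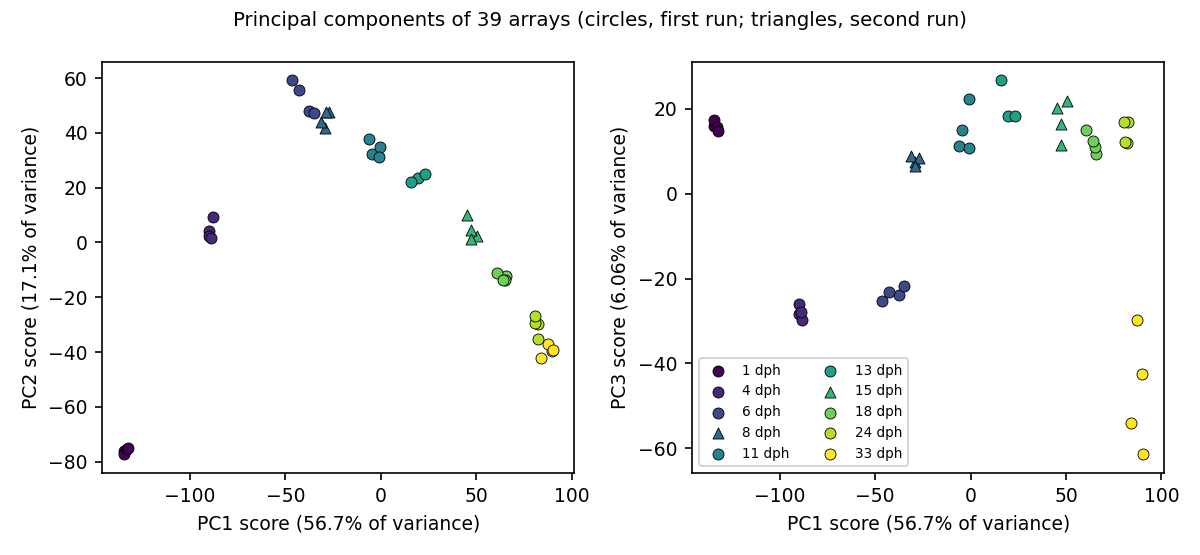
Scores of the 39 arrays on the first principal component (x axis) against PC2 and PC3, the next 2 components (y axes), 1 point per pool, coloured by age, with circles for the first scan run and triangles for the second. Ages lie in order along the first component, from a mean of -133.6 at 1 dph to 87.9 at 33 dph, and the 4 pools of 33 dph spread along PC3.

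Of 13253 probes tested, 12733 (96.1%) differed among the 10 ages (limma moderated F test, Benjamini-Hochberg adjustment). The highest and lowest age means of such a probe were a median of 1.44 apart on the log2 scale. The range reached 2-fold for 9310 probes, 8-fold for 1773 and 64-fold for 474. These ranges, and the counts of changes by fold below, use the age means without the bound. Where an age was not well above background, the size of such a fold was not measured.

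The comparison of 33 with 1 dph spans the whole series. At 33 dph, 4937 probes were higher and 5396 lower than at 1 dph, together 10333 (78.0% of those tested). The order of rises and falls depended on the scaling: the authors' table gave 5315 higher and 4898 lower, and quantile normalization 4171 and 6304. Among changes of at least 8-fold, rises outnumbered falls: 976 probes were higher and 228 lower. All 3 other scalings gave this order too, with 517 and 127 under normexp with quantile normalization. Changes of at least 2-fold comprised 3064 rises and 2729 falls here, and 3259 and 2339 in the authors' table. Their order turned after quantile normalization (2577 and 3359) and after normexp with quantile normalization (2196 and 2356). A group of 290 higher probes was not well above background on any array at 1 dph and was well above it on every array at 33 dph, with a median bound of at least 24.6-fold. In the other direction, 81 probes were not well above background on any array at 33 dph, with a median bound of at least 2.30-fold. P_isotig20811 (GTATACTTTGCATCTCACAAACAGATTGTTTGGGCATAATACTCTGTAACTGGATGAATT) was not well above background on any array at 1 dph and was at least 8758-fold higher at 33 dph (limma adjusted p = 4.8e-32), where its log2 signal was 6.08 ± 0.489 (SD, n = 4). N_isotig01905 (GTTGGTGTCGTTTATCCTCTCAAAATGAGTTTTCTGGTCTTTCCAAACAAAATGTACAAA) was likewise at least 5409-fold higher (adjusted p = 7e-31). Its mean log2 signal was -4.20 at 4 dph, with replicate D above the other 3 at -3.37, then -0.48 at 6 dph and 7.25 at 24 dph, before 5.38 ± 0.640 (SD, n = 4) at 33 dph. Among the falls, N_isotig08548 (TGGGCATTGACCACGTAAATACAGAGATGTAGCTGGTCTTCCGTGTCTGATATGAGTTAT) was measured on both sides and went from 6.47 ± 0.582 to -4.05 ± 0.453 (SD, n = 4 each), a log2 change of -10.53 (SE 0.364, adjusted p = 5.5e-23). N_isotig15627 (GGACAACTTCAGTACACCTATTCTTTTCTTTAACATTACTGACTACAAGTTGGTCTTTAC) stood at 4.28 ± 0.118 (SD, n = 4) at 1 dph. It was not well above background on any array at 18, 24 and 33 dph, and was at least 1648-fold lower at 33 dph (adjusted p = 1e-20). Of the 10 rises and 10 falls taken by the model's log2 change, 8 rises and 6 falls had a side that was not well above background on any array. With slide as a block, 10290 probes were called; within slide 3 the count was 8649 and within slide 4, on 3 arrays of these ages, it was 5693.

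The first step, from 1 to 4 dph, covers the days just after hatching. At 4 dph, 3122 probes were higher and 3210 lower than at 1 dph (6332 in all), against 3296 and 3006 with the authors' values and 2779 and 3979 after quantile normalization. Among changes of at least 2-fold, 1425 were rises and 419 were falls, and among those of at least 8-fold 252 were rises and 19 were falls. Of all called rises of any size, 94 probes went from not well above background on any array to well above it on every array. Their median bound was at least 7-fold. N_isotig03975 (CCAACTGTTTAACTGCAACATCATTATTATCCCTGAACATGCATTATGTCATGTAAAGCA) was one of them, at least 908-fold higher (adjusted p = 1.5e-29), and its mean log2 signal went from 2.81 at 4 dph to 6.12 at 18 dph. P_isotig15342 (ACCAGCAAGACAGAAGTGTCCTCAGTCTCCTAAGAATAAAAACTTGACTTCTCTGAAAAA) rose from -5.52 ± 0.615 to 3.55 ± 0.101 (SD, n = 4 each; log2 change 9.07, SE 0.314, adjusted p = 3.2e-22). This probe was highest at 4 dph: its mean was -1.04 at 11 dph, and no array measured it well above background at 24 or 33 dph. N_isotig09202 (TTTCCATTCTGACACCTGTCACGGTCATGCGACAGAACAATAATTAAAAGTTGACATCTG) stood at 1.67 ± 0.245 (SD, n = 4) at 1 dph and was at least 350-fold lower at 4 dph (adjusted p = 1.9e-20). N_isotig08469 (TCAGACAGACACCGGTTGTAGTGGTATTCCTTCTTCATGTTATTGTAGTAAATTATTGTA) fell from 1.41 ± 0.146 to -3.96 ± 1.23 (SD, n = 4 each; log2 change -5.37, SE 0.468, adjusted p = 1.3e-11), with a change of -4.77 without replicate C of 4 dph. With slide as a block 6017 probes were called, and within slide 3 alone 3055. The count on slide 1, which held only 1 array of 1 dph, rests on that lone array and is given only among the single slides below.

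Between 4 and 11 dph, 3174 probes rose and 3371 fell (6545 in all), against 3376 and 3148 with the authors' values and 2738 and 4030 after quantile normalization. Changes of at least 2-fold comprised 1218 rises and 583 falls. Of all called rises, 101 probes went from not well above background on any array to well above it on every array. Their median bound was at least 4.08-fold. P_isotig03267 (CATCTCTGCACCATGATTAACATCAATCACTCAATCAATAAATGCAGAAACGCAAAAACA) rose from -4.45 ± 0.263 to 5.18 ± 0.073 (SD, n = 4 each; log2 change 9.63, SE 0.16, adjusted p = 2.2e-30), with means of -1.42 at 6 dph, 3.74 at 8 dph and 6.74 at 24 dph. P_isotig05384 (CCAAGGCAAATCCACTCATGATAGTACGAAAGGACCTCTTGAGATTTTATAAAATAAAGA) was at least 705-fold higher at 11 than at 4 dph (adjusted p = 3e-06). It varied widely between pools of some ages, with 0.88 ± 4.77 at 8 dph and 1.99 ± 4.74 at 24 dph (SD, n = 4 each), against 5.20 ± 0.584 (SD, n = 4) at 6 dph, and it was not well above background on any array at 33 dph. N_isotig03227 (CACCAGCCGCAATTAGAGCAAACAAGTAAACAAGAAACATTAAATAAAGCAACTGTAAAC) fell from 3.18 ± 0.557 to -4.69 ± 0.148 (SD, n = 4 each; log2 change -7.86, SE 0.502, adjusted p = 7.1e-15). P_isotig09557 (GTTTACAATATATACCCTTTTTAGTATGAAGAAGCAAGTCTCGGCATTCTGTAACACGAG) fell from -1.43 ± 0.186 to -6.55 ± 0.224 (SD, n = 4 each; adjusted p = 1.9e-22), and its mean stood at -3.23 at 33 dph. With slide as a block 6041 probes were called, and within slide 3, where 1 array of 11 dph met 2 of 4 dph, 3060 were called.

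Between 11 and 18 dph, 3006 probes rose and 3650 fell (6656 in all). Rises of at least 2-fold numbered 1050 and falls of that size 564. Here 15 probes passed from not well above background on any array to well above it on every array, with a median bound of at least 40.9-fold, and 13 passed the other way. S_isotig22191 (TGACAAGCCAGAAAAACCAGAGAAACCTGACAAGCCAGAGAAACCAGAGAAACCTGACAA) was one of the former, at least 520-fold higher at 18 dph (adjusted p = 3.5e-19), and its mean was 3.60 at 33 dph. N_isotig10834 (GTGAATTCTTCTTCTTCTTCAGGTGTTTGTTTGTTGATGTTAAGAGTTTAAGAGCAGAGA) was near -5.85 at 11 dph and rose to 1.99 ± 0.685 (SD, n = 4; log2 change 7.85, SE 0.424, adjusted p = 2e-16), with a mean of -3.23 at 15 dph. N_isotig08548, the fall named above for the whole series, made most of its descent here, by 7.37 on the log2 scale (SE 0.364, adjusted p = 2.1e-17), from 4.79 at 11 dph to -2.58 at 18 dph. P_isotig09420 (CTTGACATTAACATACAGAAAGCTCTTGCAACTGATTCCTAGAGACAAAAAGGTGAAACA) held means between -2.70 and -0.90 up to 15 dph and was at least 31.5-fold lower at 18 than at 11 dph (adjusted p = 9.7e-15). With slide as a block 6376 probes were called and within slide 2 4958. Pools of 11 dph held 10 larvae and those of 18 dph 5. The signal of negative control spots spread more widely on replicates B, C and D of 18 dph (14.13, 10.08 and 9.001) than on A (4.775). Fewer probes were well above background there, with 11751 in B, 12437 in C and 11827 in D, against 13598 in A. Whether this lowered the count of 15 or raised that of 13 was not tested. Neither count is therefore set against those of other steps.

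Between 18 and 33 dph, 3258 probes rose and 3769 fell (7027 in all), an order that turned with the authors' values (3620 and 3413), with 888 rises and 859 falls of at least 2-fold. Only 33 rises and 23 falls reached 8-fold. From not well above background on any array to well above it on every array passed 6 probes, with a median bound of at least 2.91-fold. The dim side of this count is 18 dph, with the widely spread negative controls given above. It is therefore not set against the counts of other steps either. N_isotig07037 (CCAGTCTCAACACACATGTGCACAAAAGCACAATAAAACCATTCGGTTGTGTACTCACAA) rose from -3.88 ± 0.886 to 1.96 ± 0.401 (SD, n = 4 each; log2 change 5.84, SE 0.553, adjusted p = 3.9e-10), after means between -3.80 and -3.05 from 6 to 15 dph, where replicate B of 15 dph stood below the others at -4.46. The change was 4.88 with slide as a block. N_isotig16335 (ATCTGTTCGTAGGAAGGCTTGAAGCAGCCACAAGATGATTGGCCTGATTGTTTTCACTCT) was at least 17.9-fold higher at 33 dph (adjusted p = 6.6e-11), the only age at which every array measured it well above background. P_isotig14311 (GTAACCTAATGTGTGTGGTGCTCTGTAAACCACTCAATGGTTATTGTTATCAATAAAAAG) fell from 2.14 ± 0.478 to -4.27 ± 0.685 (SD, n = 4 each; log2 change -6.41, SE 0.277, adjusted p = 1e-17). P_isotig04123 (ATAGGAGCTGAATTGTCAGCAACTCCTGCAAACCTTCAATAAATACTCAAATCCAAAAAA) fell from 5.47 ± 0.299 to 0.32 ± 2.79 (SD, n = 4 each; log2 change -5.15, SE 0.617, adjusted p = 3.7e-08), with a change of -3.92 without replicate D of 33 dph. The 4 pools of 33 dph differed widely for this probe, with 1.76 in A, -0.18 in B, 3.07 in C and -3.36 in D. Its SE and adjusted p use the spread shared by all ages, and at the other ages the SD was at most 0.299. They therefore understate the spread between the pools of 33 dph. No slide held both ages; with slide as a block, joined through the other ages, 5488 probes were called, of which 5188 were among the 7027 with the same sign.

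**Figure D2:**
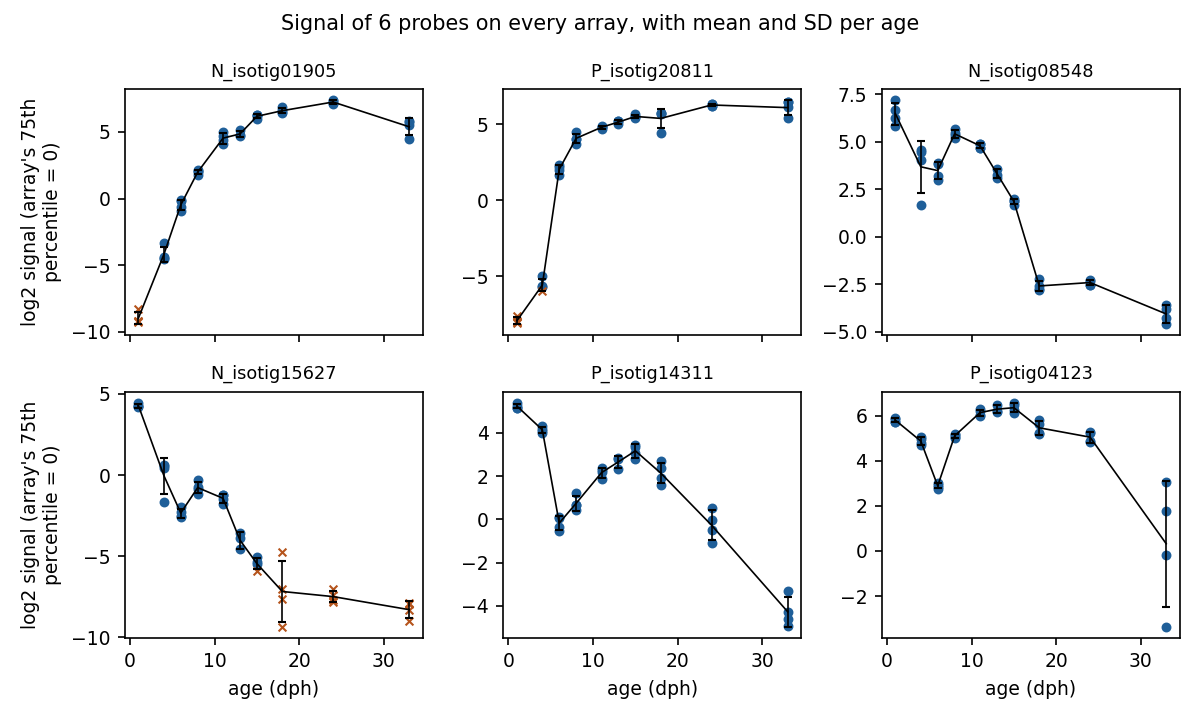
Log2 signal, relative to each array's 75th percentile (y axis), against age in dph (x axis) for 6 named probes, with blue circles for arrays well above background, orange crosses for arrays that were not, and a line with bars for the mean and SD per age. N_isotig01905 and P_isotig20811 climb from background at 1 dph, and P_isotig04123 spreads from -3.36 to 3.07 among the pools of 33 dph.

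The steps between neighbouring ages span 2 to 9 days, so their counts are not rates. They were 6332 from 1 to 4 dph, 4620 from 4 to 6 dph, 3976 from 6 to 8 dph and 3511 from 8 to 11 dph. The lowest was 1185 from 11 to 13 dph, with 735 rises and 450 falls. Counts were then 2580 from 13 to 15 dph, 2955 from 15 to 18 dph, 4754 from 18 to 24 dph and 6592 from 24 to 33 dph. Which of the first and the last step had more calls depended on the setting. The last had fewer with slide as a block (5165 against 6017), with only the arrays of the 2 ages (5635 against 6325), after quantile normalization (6646 against 6758), after normexp with quantile normalization (6557 against 6823) and at a minimum of 2-fold (1545 against 1844). Rises of at least 2-fold outnumbered falls of that size from 4 to 6 dph (821 against 187), and falls outnumbered rises from 18 to 24 dph (440 against 229), an order that turned after normexp background correction with quantile normalization (140 falls and 142 rises). The step from 11 to 13 dph has 3 pools on one side; its count was 762 without replicate A of 11 dph, 765 without replicate C of 13 dph and 556 without replicate D of 13 dph. The count from 13 to 15 dph was 1445 without replicate C of 13 dph.

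Ages 8 and 15 dph were scanned in a second run, apart from the other 8 ages, so in the 4 steps that use them run and age cannot be told apart. Scanning sessions within either run were not told apart, so steps within the first run may also hold differences between sessions. Within the first run, 4471 probes differed between 6 and 11 dph and 4185 between 13 and 18 dph. With slide as a block, the first-run counts were 4122 for 6 against 4 dph, 1001 for 13 against 11 dph, 4528 for 24 against 18 dph, 5165 for 33 against 24 dph, 4177 for 11 against 6 dph and 3812 for 18 against 13 dph. The ages 24 and 33 dph shared no slide. On single slides, with 2 to 4 arrays of the 2 ages and a lone array taken to vary like the rest, the counts were 1615 and 807 for 6 against 4 dph, 1682 and 1972 for 24 against 18 dph, 364 and 17 for 11 against 6 dph and 2122 for 18 against 13 dph. For 13 against 11 dph slide 2 gave 451 and slide 4, with 1 array of each age and the spread taken from the other ages, gave 0 with limma (308 at an unadjusted p under 0.05). With slide as a random block, the second-run steps gave 3934 for 8 against 6 dph, 3463 for 11 against 8 dph, 2509 for 15 against 13 dph and 2911 for 18 against 15 dph.

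**Figure D3:**
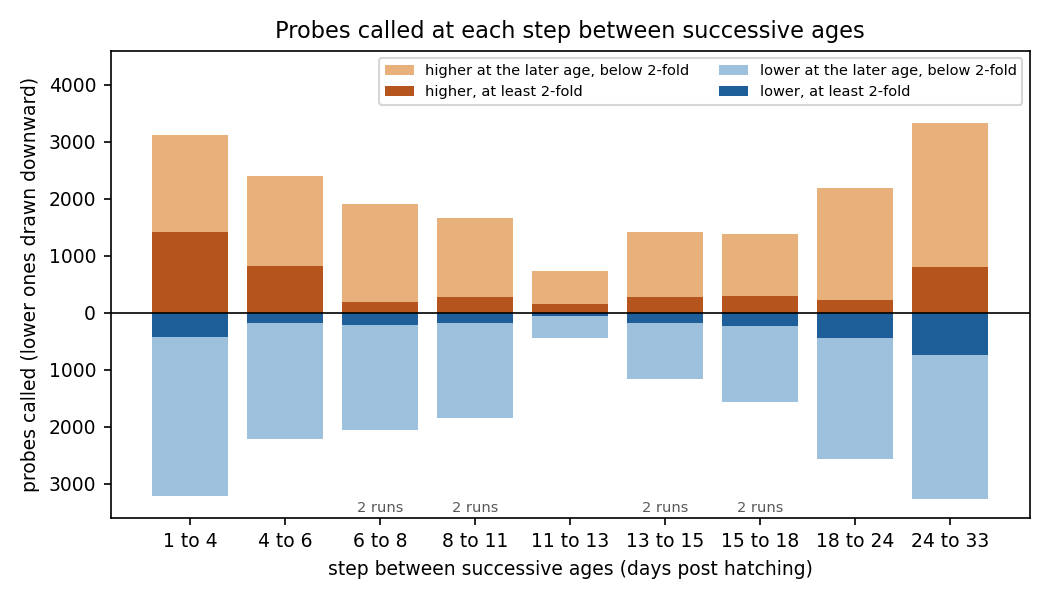
Number of probes called (y axis) at each step between successive ages in dph (x axis), with rises drawn upward and falls downward, and darker parts for changes of at least 2-fold; "2 runs" marks steps between scan runs. The count is 6332 from 1 to 4 dph, lowest at 1185 from 11 to 13 dph, and 6592 from 24 to 33 dph.

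The onset of lasting changes was set against 1 dph. A lasting rise or fall starts at the first age from which every later age, that age included, differs from 1 dph in the same direction, so a late start rests on fewer calls than an early one and does not exclude earlier differences. The comparisons of 8 and 15 dph with 1 dph set the second run against the first, so starts at these ages cannot be told apart from run. Without the arrays of 8 and 15 dph the counts by 11 dph stayed within 1.5 times. Lasting rises started at 4 dph for 1763 probes, at 6 dph for 591, at 8 dph for 216 and at 11 dph for 341, together 2911 by 11 dph. Later starts numbered 346 at 13 dph, 332 at 15 dph, 192 at 18 dph, 359 at 24 dph and 797 at 33 dph. Probes whose rise started at 4 dph had a median log2 change of 2.13 at 33 dph. For starts at 6, 8, 11 and 13 dph it was 1.67, 1.21, 1.92 and 1.60. For starts at 15, 18, 24 and 33 dph it was 0.93, 0.84, 0.66 and 0.65. Larger changes pass the threshold more readily at every age, so the definition itself ties early starts to large changes. Lasting falls by 11 dph numbered 3097, of which 1732 started at 4 dph with a median log2 change of -1.44 at 33 dph. Lasting falls that started at 33 dph numbered 915. With the authors' values, lasting rises by 11 dph (3079) outnumbered lasting falls (2706), opposite to the order given here, and quantile normalization gave 2321 rises and 3922 falls.

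**Figure D4:**
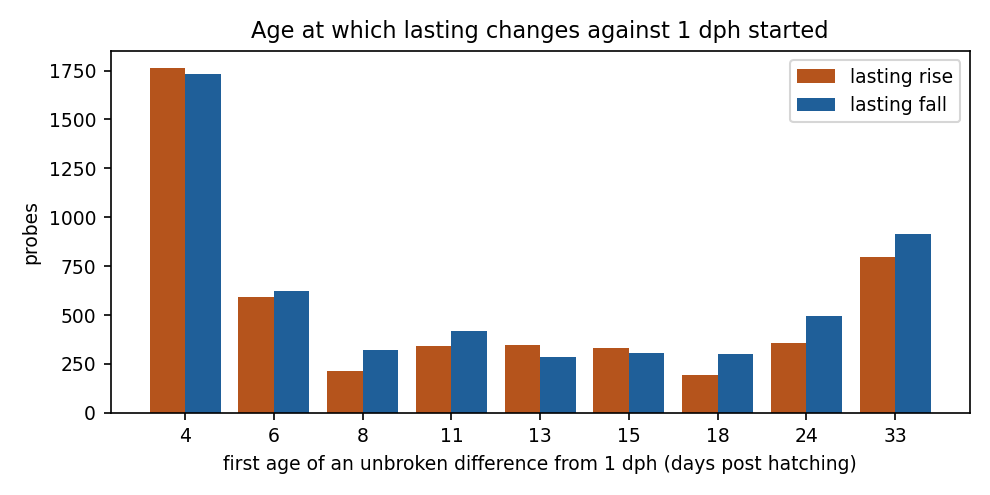
Number of probes (y axis) whose lasting rise or lasting fall against 1 dph started at each age in dph (x axis). The tallest bars are at 4 dph, with 1763 rises and 1732 falls, and the next tallest at 33 dph, with 797 and 915.

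The scaling sets the zero of each change. From 1 to 33 dph the median change over all tested probes was -0.07 on the log2 scale used here, -0.27 after quantile normalization, -0.21 after normexp with quantile normalization and 0.04 in the authors' table, and a change is to be read relative to that median. The median signal of the arrays, a different measure, rose by 0.11 here and by 0.31 in the authors' table. For 6 against 4 dph, 52.1% of the calls were rises on this scale, 39.8% after quantile normalization and 39.6% after normexp background correction with quantile normalization.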

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

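Arrays were searched for a value far from the other 3 of its age, by the gap to the nearest array over the whole range. The search covered the number of probes well above background, the raw 75th percentile, the share of signal in the 100 brightest probes, the spike-in signal and the named probes at ages where every array measured them. Of 155 groups of 4 searched, 7 held an array beyond Dixon's critical value. Chance alone would give about 1 group in 20, and 7 of 155 is no more than that share. Each was a log2 signal of a named probe. N_isotig01905 stood at -3.37 in replicate D of 4 dph, with the others between -4.57 and -4.40, and at 5.94 in replicate B of 15 dph, with the others between 6.22 and 6.27. P_isotig20811 stood at 4.40 in replicate C of 18 dph, below 5.68 to 5.71. N_isotig15627 stood at -1.69 in replicate C of 4 dph, below 0.42 to 0.61. N_isotig08469 stood at -3.35 in replicate A of 6 dph, below -2.83 to -2.75, and N_isotig03227 at 4.94 in replicate A of 1 dph, above 4.45 to 4.52. N_isotig07037 stood at -4.46 in replicate B of 15 dph, below -3.14 to -2.99.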

How the results depend on the processing

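Counts within single slides and the shuffled letters were added after the data had been seen, as were the lasting and inner-extreme counts under every setting. The planned gene-list and immune-gene results were not run for lack of gene names. Of the 20 counts, each stayed within 1.5 times under normexp with quantile normalization, quantile normalization, the authors' table, no filter on dim probes, the mean-variance trend, fewer arrays in the model and slide as a block, wherever these were run. The 20 changes of named probes kept their direction and stayed past the threshold under these and with each array left out. Their sizes moved more: by over 1.5-fold for 17 of 20 under normexp with quantile normalization, whose offset raises dim values, for 3 under quantile normalization, 2 with slide as a block and 1 with the authors' table. Under normexp P_isotig09557 changed by -3.22, N_isotig10834 by 6.18, N_isotig01905 by 9.66 and P_isotig09420 by -3.92 on the log2 scale, the last 2 below their bounds, so the bounds hold only for the scale used here. Leaving out 1 array moved 2 of the 20 by over 1.5-fold, both given with their probe. Where a probe was not well above background on any array of an age, signal over background limits its change to a bound.

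A minimum of 2-fold, which by its construction keeps fewer probes, left 5793 for 33 against 1 dph, 1844 for 4 against 1, 1801 for 11 against 4, 1614 for 18 against 11, 1747 for 33 against 18, 1008 for 6 against 4, 413 for 8 against 6, 453 for 11 against 8, 210 for 13 against 11, 453 for 15 against 13, 523 for 18 against 15, 669 for 24 against 18, 1545 for 33 against 24, 924 for 11 against 6 and 867 for 18 against 13 dph. With that minimum at every age from the start, lasting rises by 11 dph numbered 1575, lasting falls 807, inner peaks 1041 and inner troughs 518. The count over all ages, 9310, stayed within 1.5 times. Single slides, with fewer arrays, gave 5693 on slide 4 for 33 against 1 dph, 3084 and 3055 on slides 1 and 3 for 4 against 1, 3060 on slide 3 for 11 against 4, 1615 and 807 on slides 1 and 3 for 6 against 4, 451 and 0 on slides 2 and 4 for 13 against 11 (3017 and 308 at an unadjusted p under 0.05 in limma), 1682 and 1972 on slides 1 and 2 for 24 against 18, 364 and 17 on slides 3 and 4 for 11 against 6, and 2122 on slide 2 for 18 against 13 dph.

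Leaving out 1 array moved the count from 556 to 1063 for 13 against 11 dph (lowest without replicate D of 13 dph) and from 1445 to 2771 for 15 against 13 dph (lowest without replicate C of 13 dph). Every other count stayed within 1.5 times, such as 10061 to 10183 for 33 against 1 dph.

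The replicate block, with letter A to D as a term, gave 10363 probes for 33 against 1 dph and moved no count by over 1.5 times. The letters were not taken to pair the arrays, since that asks for every same-letter pair of arrays of different ages to have deviations correlating above 0.1, and 35 of 171 did. With letters shuffled 1000 times within ages, the mean was 25.5 pairs (as many in a share of 0.028), and within ages and slides 29.5 (0.0839). Of 39 arrays, 16 matched an array of their own letter best, against a mean of 9.71 (0.0579) and 12.2 (0.17). A weak link between arrays of one letter, partly shared with the slides, is not excluded.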

Other observations

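The profile counts, the contig pairs, the tests of the spike-in signal, of the total signal, of the signal share, of the slide and of progress within 33 dph were chosen after the values had been seen; the run and array noise tests and the splits of the arrays were written down before their results.

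Not every change followed age in one direction. An inner peak, an age above both 1 and 33 dph, was found for 3519 probes, 1041 of them by at least 2-fold on both sides, and an inner trough for 3125, 518 of them by at least 2-fold. Under quantile normalization troughs outnumbered peaks instead (3782 against 3160), as they did with normexp (3520 against 3295). Peaks were most frequent at 24 dph (935 probes) and 6 dph (912), with 573 at 4 dph, 524 at 18 dph, 299 at 13 dph and 276 at 11 dph. Troughs were most frequent at 24 dph (1062) and 18 dph (707). All pools of 18 and 24 dph lay on slides 1 and 2 and all pools of 33 dph on slides 3 and 4. Extremes at 18 and 24 dph may therefore partly reflect slides. With slide as a fixed block, 73.7% of the calls for 33 against 24 dph and 73.8% for 33 against 18 dph were kept. Peaks and troughs were not counted with that block. P_isotig15342, with its highest mean of 3.55 at 4 dph, is a probe of this kind.

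Calls at steps that share no arrays overlapped unevenly, while the changes of all tested probes hardly correlated. Of the probes that fell from 1 to 4 dph, 1487 also fell from 11 to 18 dph, where independent lists of these sizes give 884. Rises shared by these steps numbered 1053 against 708, while 623 probes rose first and fell later against 860, and 464 fell first and rose later against 728. For 4 against 1 and 33 against 18 dph, shared rises numbered 752 against 768, shared falls 1085 against 913, rises followed by falls 1046 against 888 and falls followed by rises 754 against 789. For 11 against 4 and 33 against 18 dph, shared rises numbered 963 against 780, shared falls 1213 against 959, rises followed by falls 816 against 903 and falls followed by rises 658 against 829. Across all tested probes, which are not independent replicates, r was 0.034, 0.0219 and 0.0551 for these pairs of steps.

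For 1846 contigs the array holds a probe with the prefix AS and another with the prefix S. Both were tested for 850 contigs, only the AS probe for 473, only the S probe for 495 and neither for 28. Over the 850, 75.5% of pairs moved in the same direction from 1 to 33 dph, called or not, and the 10 age means of a pair correlated at a median r of 0.562, with r below -0.5 for 39 pairs. Where both were called at 33 against 1 dph, 361 of 408 pairs moved in the same direction (88.5%), against a median of 50.7% and a highest of 58.2% when S probes were reassigned at random 100 times. Opposite directions were found for 47 pairs, 12 of them with both changes of at least 2-fold. Which strand each prefix stands for was not given, so these 47 were not read further.

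Chance was weighed by regrouping the arrays. For each of the 15 pairs of ages, 1 of the 35 splits of the arrays, the real one, gave as many probes. That is the smallest share that 35 splits can give, and it was not adjusted for the 15 pairs. A mixed split also puts the difference between the ages into the spread. The splits alone therefore do not exclude chance for each single count. Real counts and the highest of the other splits were 10333 and 6152 for 33 against 1 dph, 6332 and 1282 for 4 against 1, 6545 and 852 for 11 against 4, 6656 and 1557 for 18 against 11, and 7027 and 3102 for 33 against 18. For the other pairs they were 4620 and 662 for 6 against 4, 3976 and 19 for 8 against 6, 3511 and 3 for 11 against 8, 1185 and 411 for 13 against 11, 2580 and 1831 for 15 against 13, 2955 and 545 for 18 against 15, 4754 and 864 for 24 against 18, 6592 and 3156 for 33 against 24, 4471 and 1884 for 11 against 6, and 4185 and 2704 for 18 against 13 dph. Of 100 assignments of the 39 arrays to ages, the real one included, 1 gave as many probes that differ among ages (12733, highest other 4842). The same held for inner peaks (3519, highest other 466) and inner troughs (3125, highest other 990). Lasting rises (2911) and falls (3097) need calls at many ages together; the highest of the other assignments was 0 for both, which the definition makes nearly certain, so nothing is drawn from it.

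The steps that use 8 or 15 dph compare 2 scan runs. A run effect common to both ages would move them off their neighbours in the same probes. Whether 8 and 15 dph were scanned in the same session was not checked. The deviation of 8 dph from the mean of 6 and 11 dph and that of 15 dph from the mean of 13 and 18 dph, which share no arrays, correlated at r = 0.179 across probes. Comparable pairs of first-run ages gave between -0.113 and 0.111. The value lies between the bounds set in advance, 0.1 and 0.3, so a run effect on part of these calls stays open and cannot be told apart from age. The runs did differ in raw spike-in signal. Its mean on the log2 scale was 13.36 at 8 dph and 12.97 at 15 dph, against 14.09 to 14.72 at the first-run ages.

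The raw 75th percentile of the signal differed by -0.689 on the log2 scale between 24 and 33 dph and 1 and 4 dph (8 arrays each, first run; exact two-sided permutation p = 0.000155, the smallest possible), and by -0.761 to -0.627 within slides 1, 3 and 4. The permutation p-values here take single arrays as the unit, although arrays of one age belong together. They do not measure the spread between ages. Weaker labelling or scanning would dim the spike-in controls alike, yet their log2 signal differed by 0.305 in the other direction (exact permutation p = 0.065), and by 0.09 to 0.268 within these slides. The total signal differed by -0.082 on the log2 scale (exact permutation p = 0.134). The 100 brightest probes held a mean of 36.0% of the signal at the later ages and 28.7% at the earlier, a difference of 7.36 percentage points (exact permutation p = 0.000155), with no overlap between arrays and 6.20 to 7.62 points within slides. That share alone covers little of the lower percentile: the log2 share of signal outside the 100 probes differed by -0.157, against the -0.689 above. Over the first-run age means the log2 75th percentile and the share correlated at r = -0.917. A higher share still did not always go with a lower percentile. From 4 to 11 dph the share rose from 29.0% to 31.7% while the log2 75th percentile differed by -0.002. In the second run, a share of 34.03% at 8 dph stood beside the highest mean 75th percentile of any age, 2515. At 15 dph, in the same run, a share of 35.53% stood beside 1919.5. The spike-in signal differed between the runs, so these raw levels cannot be set against those of the first run. Among arrays of the same age the percentile and the share correlated at r = -0.788 (31 first-run arrays, each taken from its age mean), so the share also varied with the single array. Whether a larger share of few probes lowered the percentile therefore stays open, as does a difference that came with age; the amount of RNA per larva was not tested.

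The 33 dph pools differed from each other along the change that separates 33 from 24 dph. Over the 6 pairs of pools, the difference between a pair correlated across probes with the change from 24 dph to the other 2 pools at a median size of r of 0.286, from 0.089 for B and D up to 0.469 for C and D. Pairs of pools at the other ages gave a median of 0.057 against the same change, which argues against array noise common to all ages. By age, however, the median ran from 0.034 at 1 dph to 0.122 at 24 dph and 0.235 at 13 dph (3 pairs), so differences of the kind seen at 13 dph stay open. Both pairs that shared a slide differed in this way, the smaller at 0.258, little above the 0.241 of the highest pair of the other ages, which argues against the slides as the whole cause. Pools of 5 larvae that had moved unequally far through the change may account for this, but the median stayed under the 0.3 that was asked for, so that hypothesis stays open, as do other differences between the pools.

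At 33 dph, 74 probes well above background on every array had an SD above 1 on the log2 scale, against 25 to 55 at the other ages. Of these 74, 59 lay above their own mean in pool C and 56 in pool A, against 18 in B and 14 in D. At 33 against 24 dph, 41 of them were called lower and 7 higher, while over all tested probes 3265 were lower and 3327 higher. P_isotig04123, with 3.07 in C and -3.36 in D, was among the named probes with this spread.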
